A study of Mus musculus with 18 samples.

How the data were processed

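XCR1+ dendritic cells were sorted from mouse thymus as CCR7- or CCR7+ cells and measured on 18 Affymetrix Mouse Gene ST arrays, 3 for each of 6 groups. Per the labels, RNA was amplified with the NuGEN Ovation Pico kit, and the deposited values are log2 intensities from RMA in the oligo package. The versions used, and whether all arrays were normalised together, are not given in the sources used here. The letters in the array codes of the replicate 2 CTRL pair are inverted relative to the others; the stage stated in the labels was used. The codes of all 6 GF, 4 of 6 Ifnar1-KO and 2 of 6 CTRL arrays end in an r whose meaning is not given, so this mark largely goes with GF minus CTRL.

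The table held 35556 probesets. Those with exactly 1 gene symbol (21789) were kept, while 1621 with several symbols and 12146 without one were left out. For 999 genes with more than 1 probeset the probeset with the highest mean was used, which gave 19938 genes. No gene was filtered by level. Values were not normalised again. An array has no read depth; the median 95% half-width of a maturation change was 0.27 and that of a difference of changes 0.38.

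Linear models were fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with 1 mean per group, 12 residual degrees of freedom and 14.4 after eBayes. The 9 comparisons were maturation (CCR7+ minus CCR7-) in each background, the difference of that change from CTRL for Ifnar1-KO and GF, and Ifnar1-KO minus CTRL and GF minus CTRL in each stage. Called genes had a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Genes named from the ranked results were the 10 per direction with the largest called maturation changes in CTRL. They were taken only from genes whose 9 CCR7+ arrays, over all backgrounds, all lay on one side of the 9 CCR7- arrays. In comparisons between backgrounds the called genes with the largest changes were named without this condition. Members with the largest changes in each list, the sort genes and Ifnar1 were also named. Other genes named are marked as chosen after seeing the values or are the smallest p-values. Predicted genes, clones and small RNAs were not named.

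A total of 30 gene lists were fixed from general knowledge and tested with camera (preset correlation 0.01, adjusted over the lists of a comparison), with camera using a correlation estimated per list, and with fry. Members were also adjusted over the list alone. Thymocyte and other cell markers were among the lists. The size of maturation was scored on genes called in the background not compared, with an exact permutation of the background labels within each stage (400 relabelings); it treats the stages as independent and does not keep replicate pairs together, although the pairs of CTRL and Ifnar1-KO met the rule for pairing. The functions were tested on simulated data with known changes of log2 1 and 2. Groups, comparisons, lists and most alternative fits were chosen before the data were examined.

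The alternatives were an intensity trend, array weights, genes at or above the median level, arrays centred on their medians, the mean of all probesets, every probeset on its own, only the groups compared, a replicate block, the trailing r as covariate, and leaving out each array. Pairing by replicate number was checked before the block fits: it was asked that every pair of a background have a correlation of deviations across stages above 0.1. The pairs of CTRL (0.188, 0.147 and 0.1, rounded) and Ifnar1-KO (0.284, 0.321 and 0.236) met this, as did GF pair 1 (0.267), while GF pairs 2 and 3 (0.00354 and 0.0296) did not. The unpaired model was kept as the main one for all backgrounds, with the blocked values beside it. For comparisons between backgrounds within a stage, the replicate block was the replicate number alone, shared by all groups. Arrays of one number did not vary together across backgrounds: their deviations correlated with those of CTRL at -0.274 to 0.0233. That block therefore has no pairing to allow for. Removal of both Ifnar1-KO replicate 2 arrays, the count without sex-linked genes and the fit averaged over stages (block correlation 0.149) were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (pandas 2.3.3, numpy 2.4.6).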

Results

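Gene expression was measured on 18 Affymetrix mouse whole-transcript arrays of XCR1+ dendritic cells (DCs) sorted from the thymus. XCR1+ DCs are the DC type that takes up dying cells and cross-presents their antigens to CD8 T cells. The arrays form 6 groups of 3, from 2 stages and 3 backgrounds. The stages were immature cells (CCR7-, CD117+) and homeostatically matured cells (CCR7+, CD117-). The backgrounds were wild-type mice kept free of specific pathogens (CTRL), mice lacking the type I interferon receptor chain IFNAR1 under the same housing (Ifnar1-KO), and germ-free wild-type mice (GF). Stage separated the arrays along a first principal component with 86.9% of the variance of the 2000 genes used. Correlations were 0.974 to 0.996 between arrays of a group and 0.905 to 0.939 between stages. A second component (4.20% of the variance) set apart Ifnar1-KO replicate 2 (-20.91 in CCR7- and -18.01 in CCR7+ cells) and GF replicates 2 and 3 (-12.58 and -11.41 in CCR7-, -6.86 and -12.34 in CCR7+ cells) from the 12 other arrays (3.57 to 10.92). The labels do not say whether the 3 arrays of a group came from separate mice, so p-values measure only the spread between arrays. Values are log2 changes ± SE from limma with n = 3 arrays per group, unless stated otherwise. Each SE uses 1 spread per gene pooled over all 6 groups, although spreads differed between groups. For example, the SD of Xcr1 was 0.09 in CTRL CCR7+ and 1.78 in Ifnar1-KO CCR7+ cells.

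The first question was how XCR1+ DCs change during homeostatic maturation, compared as CCR7+ minus CCR7- cells. In CTRL mice the sort markers moved with the gates: Ccr7 (probeset 10390763), the receptor that guides DCs to lymphoid T cell areas, rose 7.98-fold from a mean of 8.99 ± 0.04 to 11.98 ± 0.09 (± SD), and Kit (10522530), which encodes CD117, fell by 3.17 ± 0.34. The largest measured rises were in Stat4, a transcription factor of interleukin 12 signalling, at 5.98 ± 0.17 or a measured 63.2-fold, Insl6 at 5.96 ± 0.30, the protease inhibitor Serpinb1a at 5.21 ± 0.24, and the T cell costimulator Tnfrsf4 (OX40) at 5.05 ± 0.26. The largest measured falls were in the lysosomal amidase Naaa at -5.58 ± 0.59, the late endosomal GTPase Rab7b at -5.45 ± 0.37, the double-stranded RNA sensor Tlr3 at -5.20 ± 0.22, the nucleotide receptor P2ry6 at -5.13 ± 0.33, and Xcr1, the chemokine receptor that defines the cells, at -5.11 ± 0.60 or a fold of 34.5. Adjusted p-values of these genes lay between 4.11e-11 for Stat4 and 1.37e-05 for Xcr1. The ranked genes were taken only from called genes whose 9 CCR7+ arrays all lay on one side of all 9 CCR7- arrays. Their separation was therefore fixed in advance, and larger changes without it would not be listed. Ccr7 and Kit, on which the cells were sorted, separated in the same way. Some of these changes start or end near background: the Y-linked Kdm5d read 3.89 to 4.62 on CTRL arrays, which had no signal of Y-linked Eif2s3y (3.34 to 3.49), while Stat4 (4.25) and Insl6 (4.58) lay in that range in CCR7- cells and Tlr3 (4.42) in CCR7+ cells. Background differs between probesets, and Stat4 read 3.73 on Ifnar1-KO CCR7- replicate 1. Their changes may therefore be lower bounds, and the order among the largest changes was not settled. The same applies to every other gene named below, in any background, whose mean in 1 of the groups compared lies in that range.

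Other genes with large measured rises in CTRL were Scin (scinderin, which severs actin filaments) at 4.92 ± 0.23, Papss2 (sulfate donor synthesis) at 4.88 ± 0.31, Socs2 (a brake on cytokine signalling) at 4.82 ± 0.37, Pygl (glycogen breakdown) at 4.81 ± 0.22, Slco5a1 at 4.78 ± 0.23 and Glipr2 at 4.78 ± 0.22. Scin, Pygl and Slco5a1 also lay within the range of Kdm5d in CCR7- cells, so their rises may be lower bounds. Large falls also covered the nucleotide receptor P2ry14 at -4.84 ± 0.35, the ectonucleotidase Entpd1 (CD39) at -5.07 ± 0.49, Havcr2 (TIM-3) at -4.93 ± 0.40, Anxa1 at -4.92 ± 0.47 and the scavenger receptor Cd36 at -4.89 ± 0.45. Of the other sort genes, Itgax (CD11c) fell by 3.13 ± 0.34, Cd8a fell by 0.73 ± 0.18, and Itgam (CD11b) had an adjusted p of 0.761. Sirpa (CD172a) rose by 0.89 ± 0.28, with an adjusted p of 0.0296. The Sirpa call ended without CTRL CCR7- replicate 2 (0.74), CTRL CCR7- replicate 3 (0.83), CTRL CCR7+ replicate 1 (0.64) or CTRL CCR7+ replicate 3 (0.88), and with each array centred on its median (0.79) or only the groups of the comparison fitted.

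**Figure D1:**
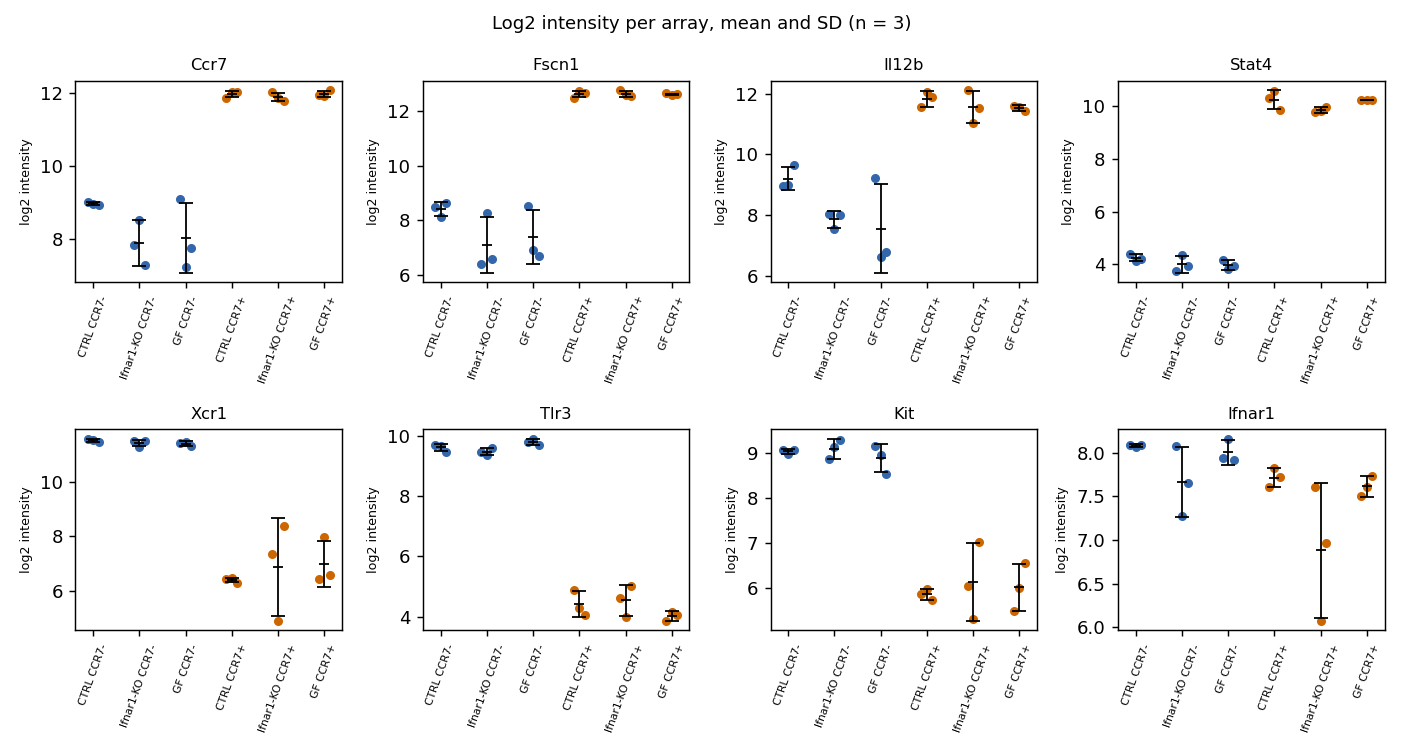
Log2 intensity on each array (points, y axis) with group mean and SD (bars, n = 3) for 8 genes, by group on the x axis; CCR7- groups are blue and CCR7+ groups orange. Ccr7, Fscn1, Il12b and Stat4 were higher and Xcr1, Tlr3 and Kit lower on all 9 CCR7+ arrays than on all 9 CCR7- arrays. For Stat4, Xcr1 and Tlr3 this was a condition of being named.

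Genes known to mark mature DCs of many tissues rose together in CTRL: 27 of 28 measured members rose, 0 fell, and 27 were called when adjusted over the list alone. Examples besides Stat4 were Socs2, Slco5a1 and Nudt17 (4.77 ± 0.25). The list ranked above other genes by camera (adjusted p 1.92e-24), and adjusted p = 0.0488 with an estimated correlation. Of 23 genes of the NF-kB family and its targets, 22 rose and 0 fell (22 adjusted over the list alone). Among them were Relb, the DC-associated NF-kB subunit, at 2.89 ± 0.21, the survival factor Bcl2l1 at 2.06 ± 0.30 and the adaptor Traf1 at 1.93 ± 0.17. Camera gave an adjusted p of 6.65e-12, and adjusted p = 0.08 with an estimated correlation. Of 20 costimulatory and coinhibitory genes, 12 rose and 5 fell (19 adjusted over the list alone); camera gave an adjusted p of 0.00182, and adjusted p = 0.184 with an estimated correlation. Slamf1 (4.25 ± 0.30) and Pdcd1lg2, which encodes PD-L2 (4.18 ± 0.28), rose beside Tnfrsf4, while Havcr2 fell.

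Of 22 migration and cytoskeleton genes, 13 rose and 5 fell in CTRL (20 adjusted over the list alone). Fscn1, the actin-bundling protein of mature DC dendrites, rose by 4.20 ± 0.45, Tubb2b by 3.27 ± 0.32 and Actn1 by 3.07 ± 0.39. The camera adjusted p was 0.0171, and adjusted p = 0.202 with an estimated correlation. Of 25 chemokines and cytokines, 13 rose and 6 fell (20 adjusted over the list alone). The T cell attractant Ccl5 rose by 4.61 ± 0.33 and the CCR7 ligand Ccl19 by 4.04 ± 0.23, while Il1b changed by -3.64 ± 0.44 and Il18 by -3.51 ± 0.24; the list did not pass camera (adjusted p 0.21). Of 19 genes related to regulatory T cells and tolerance, 10 rose and 2 fell (13 adjusted over the list alone). Besides Socs2 and Pdcd1lg2, the prostaglandin synthase Ptgs2 rose by 3.75 ± 0.23 and Cd274 (PD-L1) by 3.72 ± 0.36. Camera gave an adjusted p of 0.0034, and adjusted p = 0.0816 with an estimated correlation.

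XCR1+ DC identity genes fell as a group in CTRL: 23 of 29 fell and 3 rose (26 adjusted over the list alone), led by Naaa, Rab7b, Tlr3 and Xcr1. The camera adjusted p was 1.09e-16, and adjusted p = 0.0488 with an estimated correlation. Cell cycle genes fell by a list median of -2.56: 35 of 39 fell and 0 rose (38 adjusted over the list alone). The mitotic cyclin Ccnb2 changed by -4.70 ± 0.42, the kinesin Kif23 by -4.44 ± 0.37, Ccna2 by -4.20 ± 0.42 and the checkpoint kinase Bub1 by -4.11 ± 0.29. Camera gave an adjusted p of 4.38e-33, and adjusted p = 0.0183 with an estimated correlation. Among 16 MHC class II pathway genes, 5 rose and 8 fell (14 adjusted over the list alone). The protease Lgmn rose by 3.46 ± 0.21, while the class II transactivator Ciita changed by -3.42 ± 0.21 and H2-DMa by -2.98 ± 0.23; the list did not pass camera (adjusted p 0.0744). Among 18 MHC class I pathway genes, 7 rose and 4 fell (13 adjusted over the list alone; camera adjusted p 0.384). Wdfy4, needed for cross-presentation, changed by -4.69 ± 0.40, and Tapbpl, a peptide editor, by 1.88 ± 0.14.

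Interferon-related genes went both ways in CTRL maturation. Of 54 type I interferon stimulated genes, 8 rose, 18 fell and 28 did not pass (32 adjusted over the list alone). Epsti1 rose by 3.16 ± 0.18, while the DNA-sensing family members Ifi205 and Ifi203 changed by -3.01 ± 0.29 and -2.74 ± 0.28. The list lay below other genes by camera (adjusted p 0.0128), and adjusted p = 0.565 with an estimated correlation. Of 18 interferon gamma stimulated genes, 8 rose and 3 fell (14 adjusted over the list alone), among them the guanylate-binding proteins Gbp5 at 4.24 ± 0.25 and Gbp4 at 3.96 ± 0.29. Camera gave an adjusted p of 0.0212, and adjusted p = 0.202 with an estimated correlation. Of 25 interferon receptors, sensors and factors, 3 rose and 7 fell (11 adjusted over the list alone), with Irf1 at 3.17 ± 0.25, Ifngr1 at -2.85 ± 0.24 and Myd88 at -1.69 ± 0.22 beside Tlr3. Their camera adjusted p was 0.0212, and adjusted p = 0.128 with an estimated correlation.

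Thymocyte markers were also higher on CCR7+ arrays of CTRL mice: of 20 markers, 5 rose and 0 fell (5 adjusted over the list alone), with a list median of 1.13. Camera gave an adjusted p of 0.0178, and adjusted p = 0.565 with an estimated correlation. Cd3d, a T cell receptor subunit, had 1.84 ± 0.78 (adjusted p 0.0967) and did not pass. The mean marker level per array was 4.59 to 4.96 on CTRL CCR7- and 5.37 to 6.12 on CTRL CCR7+ arrays, and it reached 7.90 on Ifnar1-KO CCR7+ replicate 2.

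In total, 5218 of 19938 genes were called in CTRL at an adjusted p under 0.05 by limma, 2514 higher and 2704 lower in CCR7+ cells; 903 rose and 1484 fell by a log2 change of at least 1. With each array centred on its median, 1669 were higher and 3157 lower. Blocked by background and replicate number, so that CCR7- and CCR7+ arrays of one number were paired, 5556 genes were called with this replicate block. Without both Ifnar1-KO replicate 2 arrays, a choice made after seeing the data, 5829 genes were called. With an estimated correlation, camera calls held for the mature DC, identity and cell cycle lists in CTRL. In Ifnar1-KO maturation they held for these and for the lists of costimulation, NF-kB, migration, tolerance, interferon gamma stimulated genes, survival and the chromosome 16 neighbours of Ifnar1. In GF maturation they held for 6 lists: mature DC, NF-kB, tolerance, identity, cell cycle and the chromosome 16 neighbours. With the replicate block the genes next to Ifnar1 on chromosome 16 were no longer called in Ifnar1-KO maturation (camera adjusted p 0.0704), nor without Ifnar1-KO CCR7+ replicate 2 (0.188) or Ifnar1-KO CCR7- replicate 3 (0.0621), nor in GF maturation without GF CCR7+ replicate 2 (0.0533). In the background comparisons within a stage they held for MHC class II and sex-linked genes in Ifnar1-KO minus CTRL CCR7+ cells and for sex-linked genes in GF minus CTRL CCR7+ cells, and in no other comparison.

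The study's next question was whether this maturation needs type I interferon signalling. Ifnar1-KO and CTRL arrays also differed in sex-linked genes, as described below, so comparisons between them may include effects of sex. The target gene was examined first. The Ifnar1 probeset (10436849, chromosome 16) read 8.07, 7.27 and 7.66 on the Ifnar1-KO CCR7- arrays against 8.06 to 8.09 in CTRL, and 7.61, 6.07 and 6.97 on the Ifnar1-KO CCR7+ arrays against 7.61 to 7.82 in CTRL. The differences were -0.41 ± 0.28 (adjusted p 0.687) in CCR7- and -0.83 ± 0.28 in CCR7+ cells, and neither passed. Ifnar1-KO replicate 1 read like CTRL at both stages, and germ-free arrays read 7.50 to 8.16. Which part of the transcript the probeset covers relative to the disrupted part of the gene is not given in the sources used here, so its level does not check the genotype labels.

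The genes of maturation rose and fell in the arrays labelled Ifnar1-KO as well. Cells of every background were sorted by CCR7 and CD117, so Ccr7 and Kit were bound to differ. The arrays compare sorted cells and do not show how many cells reached the CCR7+ stage. A need for interferon signalling to reach that stage could therefore not be seen. Stat4, Tnfrsf4, Xcr1, Naaa and Tlr3 were chosen on the arrays of all backgrounds, so their direction here was fixed in advance. Stat4 rose by 5.83 ± 0.17, Tnfrsf4 by 6.06 ± 0.26, Fscn1 by 5.55 ± 0.45, and Ccr7 from a mean of 7.89 ± 0.63 to 11.90 ± 0.12 (± SD), while Xcr1 changed by -4.54 ± 0.60, Naaa by -5.12 ± 0.59, Tlr3 by -4.92 ± 0.22 and Kit by -2.96 ± 0.34. Stat4 in CCR7- cells (4.01) and Tlr3 in CCR7+ cells (4.55) again lay in the range of Kdm5d, so their changes may be lower bounds. Of 28 mature DC genes, 27 rose (27 adjusted over the list alone; camera adjusted p 1.60e-35, and 0.0155 with an estimated correlation), including Anxa3 at 5.83 ± 0.21 and Nudt17 at 5.51 ± 0.25. Of 39 cell cycle genes, 34 fell (37 adjusted over the list alone; camera adjusted p 1.45e-30, and 0.0155 with an estimated correlation). Of 29 identity genes, 22 fell and 2 rose (24 adjusted over the list alone; camera adjusted p 1.33e-15, and 0.0297 with an estimated correlation). In all, 4036 genes were called, 1878 higher and 2158 lower; 4353 were called with the replicate block and 3802 without both Ifnar1-KO replicate 2 arrays.

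Interferon-related genes were examined next in Ifnar1-KO maturation. Of 18 interferon gamma stimulated genes, 9 rose and 3 fell (12 adjusted over the list alone), with Gbp5 at 4.78 ± 0.25, Gbp4 at 4.62 ± 0.29 and Irf1 at 3.65 ± 0.25; camera gave an adjusted p of 2.31e-05, and 0.0336 with an estimated correlation. Of 54 type I interferon stimulated genes, 15 rose, 12 fell and 27 did not pass (35 adjusted over the list alone). Epsti1 rose by 3.63 ± 0.18 and Ifit1, which binds viral RNA, by 2.13 ± 0.27, while Ms4a4c changed by -2.24 ± 0.28. The list did not pass camera (adjusted p 0.835); its median was 0.04 and its mean -0.03. Of 20 thymocyte markers, 4 rose in Ifnar1-KO maturation (8 adjusted over the list alone), with Cd8b1 at 2.74 ± 0.40. Camera gave their list an adjusted p of 3.50e-05, and adjusted p = 0.373 with an estimated correlation.

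The change itself was then compared between Ifnar1-KO and CTRL. No gene passed in limma (0 calls, smallest adjusted p 0.837), and the fit with the replicate block also called 0. At an unadjusted p under 0.05 there were 901 genes, where chance gives 997. That number was 567 without Ifnar1-KO CCR7- replicate 2 and 1601 without Ifnar1-KO CCR7- replicate 3, so it was not settled on either side of chance. The smallest p-values, none of them passing, belonged to the adhesion receptor Adgre5 (1.03 ± 0.18), Gpc1 (-0.62 ± 0.12) and the phosphatase Ptpn22 (1.55 ± 0.33). Of the 2387 genes called in CTRL with a log2 change of at least 1, 2386 had the same sign in Ifnar1-KO and 2175 (91.1%) were also called, 0 of them in the opposite direction. These calls use the spread pooled over all groups. With only its own groups fitted, Ifnar1-KO maturation had 2937 calls instead of 4036, and CTRL 6169 instead of 5218. The 91.1% was not recomputed with those fits. The 95% interval of the difference lay within a log2 change of 1 for 1143 of the 2387 genes (47.9%) and excluded 0, unadjusted, for 162 (6.79%). The median half-width of that interval over all genes was 0.38. In simulated data of this design, 56% of differences of log2 1 and 90% of those of log2 2 were called. The changed genes were drawn at random from all genes, whose median SE of a difference was 0.18. Among the named genes with the largest maturation changes it was 0.24 for Stat4 and up to 0.85 for Xcr1. These shares therefore overstate what could be called among such genes.

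A score of the maturation genes, chosen on the third background only (913 up, 1237 down), changed by 3.51 in Ifnar1-KO and 3.73 in CTRL. The difference of -0.22 was not larger than that of other labelings (two-sided exact permutation p = 0.245, 400 relabelings, which do not keep the replicate pairs together), and it was -0.33 without Ifnar1-KO CCR7+ replicate 1 and -0.08 without both Ifnar1-KO replicate 2 arrays. Across genes, the maturation changes of Ifnar1-KO and CTRL had a Pearson r of 0.947 and a Spearman correlation of 0.779. Genes are not independent replicates. For lists, camera called 14 of 30 differences between Ifnar1-KO and CTRL, of which 0 held with an estimated correlation and 0 passed fry, a test of whether a list's genes moved on balance in one direction. The type I interferon stimulated list had a median difference of 0.33 (camera adjusted p 4.61e-11, and adjusted p = 0.256 with an estimated correlation), with Oas3 at 0.82 ± 0.29 and Ifit1 at 0.81 ± 0.38. The interferon gamma stimulated list had a median of 0.44 (camera adjusted p 5.18e-06, and adjusted p = 0.0711 with an estimated correlation), with Gbp3 at 1.14 ± 0.28. No member of either list passed over all genes; adjusted over the list alone, 0 and 1 did.

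**Figure D2:**
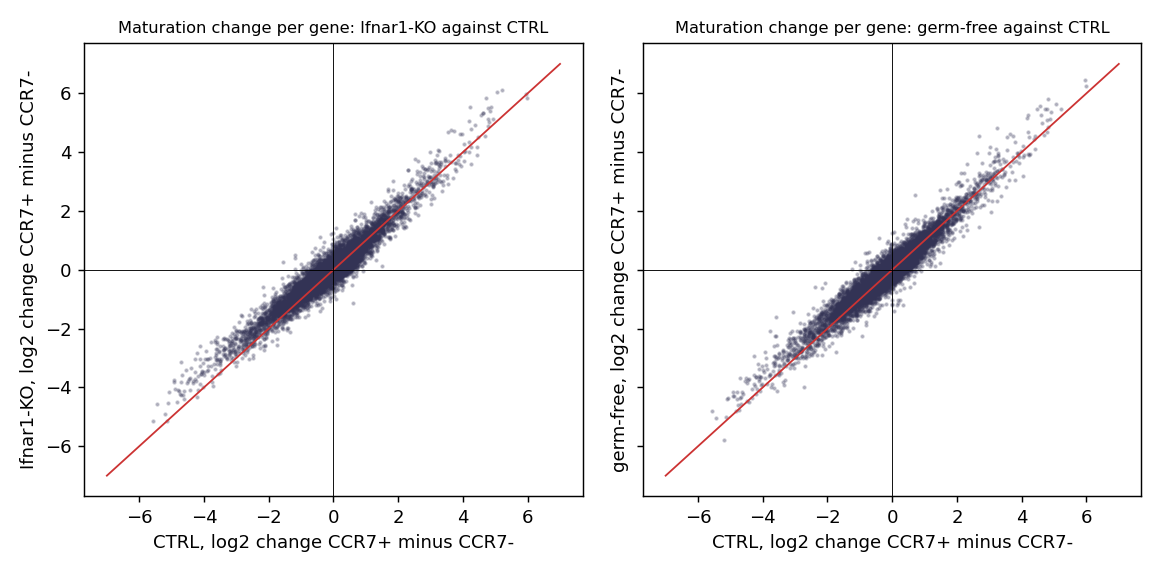
Maturation log2 change (CCR7+ minus CCR7-) of each of 19938 genes in CTRL (x axis) against Ifnar1-KO (left, y axis) and germ-free mice (right, y axis); the red line marks equal change. Pearson r across genes was 0.947 and 0.953, and the Spearman correlation was 0.779 and 0.802.

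Within a stage, few genes separated Ifnar1-KO from CTRL. In CCR7- cells limma called 0 genes, with 1401 at an unadjusted p under 0.05 where chance gives 997. The 1401 became 603 without Ifnar1-KO CCR7- replicate 2 and 2592 without Ifnar1-KO CCR7- replicate 3, so an excess over chance was not settled. The 3 smallest p-values belonged to the inhibitory receptor gene Klra5 at -0.92 ± 0.13 (adjusted p 0.0574), the Y-linked translation factor Eif2s3y at 2.63 ± 0.38 (adjusted p 0.0574) and Ifi27l2a, an interferon-induced gene, at -1.12 ± 0.17 (adjusted p 0.0665). Ifi27l2a read 10.34, 10.93 and 10.33 on the Ifnar1-KO CCR7- arrays against 11.47 to 11.77 in CTRL. A single array decided some of the count of called genes: it was 2 without Ifnar1-KO CCR7- replicate 1 and 1 without Ifnar1-KO CCR7- replicate 2 or Ifnar1-KO CCR7- replicate 3. Without both Ifnar1-KO replicate 2 arrays 1 gene was called, and with the replicate block 0. Between backgrounds this block is the replicate number alone, by which arrays of different backgrounds were not paired. In simulated data of this size, with changed genes drawn at random from all genes, 75% of changes of log2 1 and 99% of changes of log2 2 were called. Genes with a larger spread than most are called less often.

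Camera placed many gene lists in CCR7- cells lower in Ifnar1-KO than in CTRL. It called 15 of 30 lists, 13 of them lower, and 0 held with an estimated correlation. Fry called 1 list. Among genes at or above the median level, 6 of the 15 camera calls were kept. The median change was 0.043 over all genes and -0.038 over genes at or above the median level. The lower placing was therefore not told apart from a shift with signal level. The mature DC list had a median of -0.42 (camera adjusted p 7.52e-13, and adjusted p = 0.118 with an estimated correlation); 0 of 28 members passed and 2 did when adjusted over the list alone, with Fscn1 at -1.33 ± 0.45, Il12b at -1.33 ± 0.50 and Anxa3 at -1.13 ± 0.21. The interferon gamma stimulated list had a median of -0.15 (camera adjusted p 3.84e-06, and adjusted p = 0.108 with an estimated correlation), with the chemokine Cxcl10 at -1.48 ± 0.36 and Cd274 at -1.22 ± 0.36; 0 of 18 passed and 2 did adjusted over the list alone. The type I interferon stimulated list had a median of -0.12 (camera adjusted p 2.07e-05, and adjusted p = 0.376 with an estimated correlation); 0 of 54 passed and 1 did adjusted over the list alone, with Ifi27l2a, Oas1a (-0.89 ± 0.30) and Mx1 (-0.84 ± 0.66) as examples. The mean mature list level was 7.58 to 7.83 on CTRL CCR7- arrays and 7.07 to 7.39 on Ifnar1-KO CCR7- arrays, while it was 10.56 to 10.91 on the CCR7+ arrays of both backgrounds.

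In CCR7+ cells limma called 3 genes between Ifnar1-KO and CTRL, with 582 at an unadjusted p under 0.05 (488 to 1056 with 1 array left out). Eif2s3y rose by 3.88 ± 0.38 (adjusted p 0.00106), Adgre5 rose by 0.88 ± 0.13 (adjusted p 0.0381) and Gpc1, a heparan sulfate proteoglycan, changed by -0.61 ± 0.08 (adjusted p 0.0325). Eif2s3y read 3.34 to 3.49 on all 6 CTRL arrays and 5.22 to 7.84 on all 6 Ifnar1-KO arrays. The count was 7 without Ifnar1-KO CCR7+ replicate 1, and 1 without CTRL CCR7+ replicate 2, CTRL CCR7+ replicate 3 or Ifnar1-KO CCR7+ replicate 2. It was also 3 without both Ifnar1-KO replicate 2 arrays, of which only 1 was among the 3 genes called with all arrays, 1 with the replicate block and 0 when only the arrays of both groups were fitted. The calls of Adgre5 (0.74 to 0.95) and Gpc1 (-0.63 to -0.58) each ended without any single array of either group except Ifnar1-KO CCR7+ replicate 1. Ifi27l2a had -0.77 ± 0.17 (adjusted p 0.715), and averaged over both stages it was lower in Ifnar1-KO by -0.94 ± 0.12 (adjusted p 0.0107). This averaged limma fit, chosen after seeing the data, called 3 genes. The others were the Y-linked Eif2s3y (3.26) and Kdm5d (1.15). An effect of sex on Ifi27l2a was therefore not separated from that of the missing receptor.

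The MHC class II pathway list lay higher in Ifnar1-KO CCR7+ cells, with a median of 0.15 (camera adjusted p 4.50e-06, and 0.0483 with an estimated correlation). Of its 16 members 0 passed and 1 did adjusted over the list alone, with H2-Ob at 0.91 ± 0.39 and H2-DMa at 0.84 ± 0.23. H2-Ob and H2-DMa fell during maturation in CTRL, and other genes that fell then had positive values here without passing: Itgax 0.82 ± 0.34, Wdfy4 0.94 ± 0.40 and Cd36 0.84 ± 0.45. Xcr1 read 7.37, 4.90 and 8.36 on the Ifnar1-KO CCR7+ arrays against 6.31 to 6.48 in CTRL. The identity list had a median of 0.14 (camera adjusted p 0.0132, and adjusted p = 0.824 with an estimated correlation), with 0 of 29 members passing over all genes or adjusted over the list alone. This XCR1+ DC identity call ended without CTRL CCR7+ replicate 3 (0.437), Ifnar1-KO CCR7+ replicate 1 (0.622) or Ifnar1-KO CCR7+ replicate 3 (0.933). Remaining CCR7- cells or less complete maturation on these arrays were not told apart from a change in MHC class II genes. The cell cycle list had a median of 0.19 (camera adjusted p 1.27e-07, and adjusted p = 0.48 with an estimated correlation); 0 of 39 passed and 6 did adjusted over the list alone, with Ccnb2 at 1.62 ± 0.42. The type I interferon stimulated list had a median of 0.17 (camera adjusted p 9.47e-06, and adjusted p = 0.824 with an estimated correlation), with Ly6e at 0.82 ± 0.16; 0 of 54 passed and 3 did adjusted over the list alone. That list was no longer called without Ifnar1-KO CCR7+ replicate 1 (0.863). The thymocyte marker list had a median of 0.46 (camera adjusted p 4.16e-04, and adjusted p = 0.848 with an estimated correlation), with Rag1, the recombinase of developing lymphocytes, at 1.85 ± 0.90; 0 of 20 markers passed, and 0 adjusted over the list alone. The direction of the thymocyte list rested on Ifnar1-KO CCR7+ replicate 2, where Rag1 read 10.31 against 6.02 and 7.51 on the other two. Without that array the thymocyte list was called lower in Ifnar1-KO (camera adjusted p 0.0115), and without CTRL CCR7+ replicate 2 it was not called (0.22). Sex-linked genes were the other list whose call held, with an adjusted p of 0.0248 with an estimated correlation; 1 of 4 rose, and 2 passed adjusted over the list alone.

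The remaining question was whether maturation needs the microflora. Here too the arrays compare sorted cells and do not show how many cells matured. The directions of Stat4, Tnfrsf4, Tlr3, Naaa and Xcr1 were again fixed by how these genes were chosen. GF and CTRL arrays also differed in sex-linked genes, as described below, so comparisons between them include any effect of sex. In germ-free mice Stat4 rose by 6.24 ± 0.17, Tnfrsf4 by 5.63 ± 0.26, Ccr7 by 3.96 ± 0.35 and Il12b, a subunit of interleukin 12, by 3.97 ± 0.50, while Tlr3 changed by -5.77 ± 0.22, Naaa by -4.79 ± 0.59, Xcr1 by -4.39 ± 0.60 and Kit by -2.87 ± 0.34. The changes of Stat4 (3.98 in CCR7- cells) and Tlr3 (4.02 in CCR7+ cells) may again be lower bounds. Of 28 mature DC genes, 27 rose (27 adjusted over the list alone; camera adjusted p 2.72e-32, and 0.0271 with an estimated correlation). Of 23 NF-kB genes, 21 rose (21 adjusted over the list alone; camera adjusted p 1.10e-15, and 0.0398 with an estimated correlation), with Relb at 3.08 ± 0.21. Of 39 cell cycle genes, 34 fell (36 adjusted over the list alone; camera adjusted p 1.44e-31, and 0.0229 with an estimated correlation), and of 29 identity genes 22 fell and 3 rose (26 adjusted over the list alone; camera adjusted p 4.86e-16, and 0.0398 with an estimated correlation). Of 54 type I interferon stimulated genes, 8 rose and 18 fell (30 adjusted over the list alone), and the list did not pass camera (adjusted p 0.0813). Of 20 thymocyte markers, 3 rose (1 adjusted over the list alone), with Cd8b1 at 2.03 ± 0.40; camera gave an adjusted p of 0.00665, and adjusted p = 0.484 with an estimated correlation.

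In all, 4256 genes were called in germ-free maturation, 1900 higher and 2356 lower, 4555 with the replicate block and 4807 without both Ifnar1-KO replicate 2 arrays. Compared with CTRL, no gene passed for a difference in its change (0 calls in limma, smallest adjusted p 0.999, and 0 calls with the replicate block). At an unadjusted p under 0.05 there were 660, where chance gives 997. That number was 446 without GF CCR7- replicate 3 and 1311 without GF CCR7- replicate 1. The smallest p-values, not passing, were those of Tmem231 (-0.86 ± 0.16), Birc5 (1.33 ± 0.25) and Atxn10 (0.59 ± 0.12). Of the 2387 genes called in CTRL with a log2 change of at least 1, 2385 had the same sign in germ-free mice and 2211 (92.6%) were called, with 0 in the opposite direction. These calls also use the pooled spread. With only its own groups fitted, germ-free maturation had 3313 calls instead of 4256, and the 92.6% was not recomputed with that fit. The 95% interval of the difference lay within a log2 change of 1 for 1218 of the 2387 genes (51.0%) and excluded 0, unadjusted, for 141 (5.91%). The maturation score, on genes chosen in Ifnar1-KO (958 up, 1143 down), changed by 3.61 in germ-free and 3.77 in CTRL mice, a difference of -0.16 (two-sided exact permutation p = 0.25), which was -0.09 without GF CCR7+ replicate 2. Camera called 7 of 30 list differences, of which 0 held with an estimated correlation and 0 passed fry. Across all 3 backgrounds, 3080 genes were called in the same direction, 1344 higher and 1736 lower in CCR7+ cells.

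**Figure D3:**
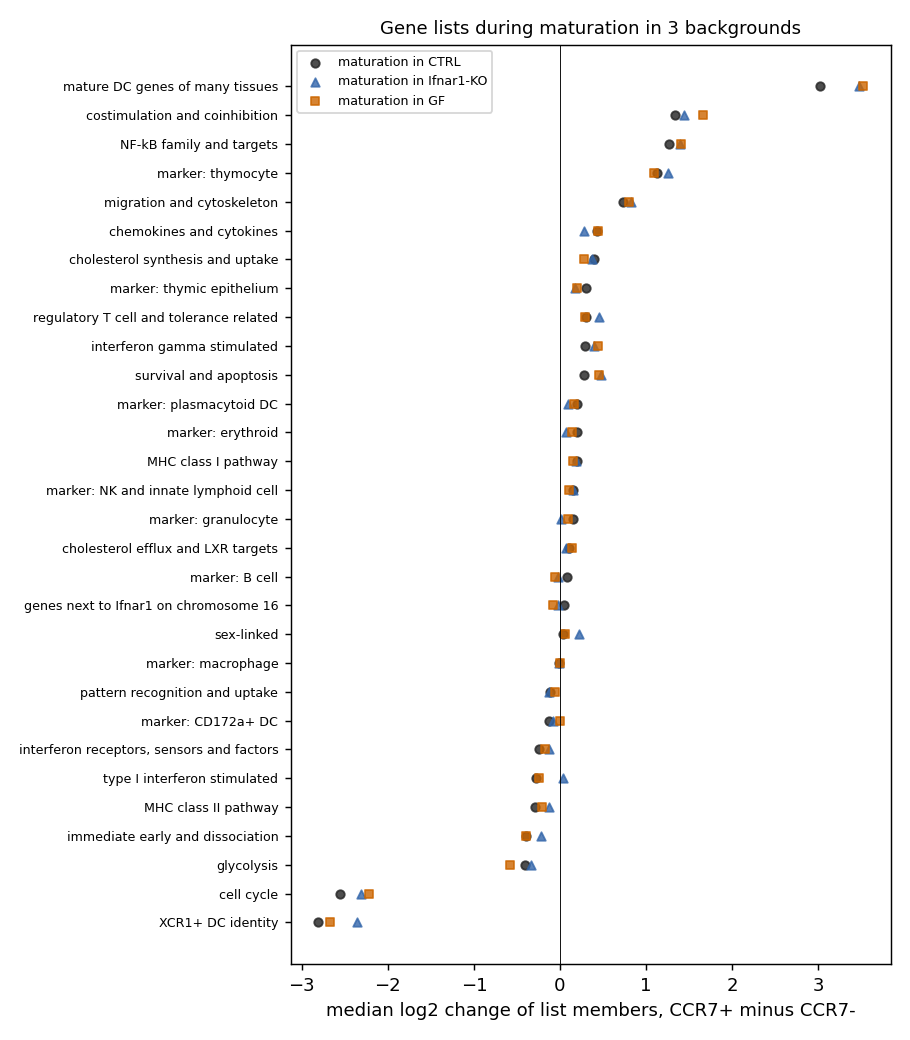
Median log2 change (x axis, CCR7+ minus CCR7-) of the measured members of 30 gene lists (y axis) in CTRL (circles), Ifnar1-KO (triangles) and germ-free mice (squares). The mature DC list lay at 3.02, 3.48 and 3.52 and the cell cycle list at -2.56, -2.31 and -2.22.

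Between germ-free and CTRL mice, sex-linked genes led the differences at both stages. In CCR7- cells 3 genes were called: Eif2s3y rose by 4.58 ± 0.38 (adjusted p 9.54e-05), the Y-linked demethylase Kdm5d rose by 2.22 ± 0.19 (adjusted p 9.54e-05) and Xist, the RNA of the inactive X chromosome, changed by -5.16 ± 0.61 (adjusted p 0.00372). Xist read 8.39 to 9.63 on the CTRL CCR7- arrays and 3.99 to 4.13 on the germ-free CCR7- arrays. The labels give no sex of the mice, but Xist and Eif2s3y set all CTRL arrays apart from all GF arrays, as female and male mice would. Germ-free housing and sex therefore cannot be told apart in these comparisons. In all, 1260 genes had an unadjusted p under 0.05, where chance gives 997. That number was 594 without GF CCR7- replicate 3 and 2769 without GF CCR7- replicate 1, so an excess over chance was not settled. Without GF CCR7- replicate 1 the count of called genes was 41, of which 35 were lower in germ-free cells. Of these, 34 were outside the list of sex-linked genes, although they include the X-linked Kdm6a and Kdm5c. Of the 35, 23 were genes called higher in CCR7+ than CCR7- cells of CTRL mice. Examples, chosen after seeing the values, were Il12b (-2.48), Cd274 (-1.53), Ccr7 (-1.48) and Ccl5 (-1.24) on the remaining arrays. The count without both Ifnar1-KO replicate 2 arrays was 7, and 3 with the replicate block.

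With all arrays, the mature DC list in germ-free CCR7- cells had a median of -0.46 against CTRL (camera adjusted p 2.36e-13, and adjusted p = 0.19 with an estimated correlation); 0 of 28 members passed and 5 did adjusted over the list alone. The list mean was 7.79 on GF CCR7- replicate 1, within the CTRL range of 7.58 to 7.83, and 6.77 and 6.92 on the other two. These other two arrays are also the ones set apart on the second component, and their upper quartiles (6.41 and 6.38) lay below those of GF CCR7- replicate 1 (6.54) and of CTRL CCR7- arrays (6.54 to 6.56), so the list difference and this array difference were not told apart. The NF-kB list had a median of -0.29 (camera adjusted p 2.44e-05, and adjusted p = 0.255 with an estimated correlation), with 0 of 23 members passing over all genes or adjusted over the list alone. The interferon gamma stimulated list had a median of -0.22 (camera adjusted p 1.74e-04, and adjusted p = 0.19 with an estimated correlation), with Irf1 at -0.77 ± 0.25 and 0 of 18 members passing either way.

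In CCR7+ cells 6 genes were called between germ-free and CTRL mice, with 1168 at an unadjusted p under 0.05 (810 to 1787 with 1 array left out). Besides Eif2s3y (5.02 ± 0.38), Kdm5d (1.92 ± 0.19) and Xist (-4.67 ± 0.61), these were Naf1, a factor of box H/ACA RNA assembly, at 1.38 ± 0.20 (adjusted p 0.0197), the mitotic survivin gene Birc5 at 1.30 ± 0.18 (adjusted p 0.0163) and Atxn10 at 0.63 ± 0.09 (adjusted p 0.0163). Naf1 read 4.34 ± 0.04 in CTRL and 5.71 ± 0.43 in germ-free CCR7+ cells (mean ± SD), and Birc5 5.48 ± 0.27 and 6.78 ± 0.19. The CTRL value of Naf1 lay in the range of Kdm5d given above, so its change may be a lower bound. The count was 13 without GF CCR7+ replicate 1 and 2 without CTRL CCR7+ replicate 3 or GF CCR7+ replicate 3; it was 1 when only the arrays of both groups were fitted, 10 without both Ifnar1-KO replicate 2 arrays and 5 with the replicate block. The call of Naf1 ended with the replicate block (change still 1.38), although arrays of different backgrounds were not paired by replicate number. It also ended with the trailing r as covariate (1.22). Nor did it stand without CTRL CCR7+ replicate 1 (1.36), CTRL CCR7+ replicate 2 (1.37), CTRL CCR7+ replicate 3 (1.39) or GF CCR7+ replicate 3 (1.14). That of Birc5 ended with the trailing r (1.23) and without CTRL CCR7+ replicate 2 (1.25), CTRL CCR7+ replicate 3 (1.19), GF CCR7+ replicate 2 (1.28) or GF CCR7+ replicate 3 (1.21). The call of Atxn10 ended with the replicate block and the trailing r (0.63 with each) and without any array of either group except GF CCR7+ replicate 1 (0.56 to 0.66). The Xist call ended without CTRL CCR7+ replicate 2 (-4.38), CTRL CCR7+ replicate 3 (-4.48) or GF CCR7+ replicate 3 (-4.52). With the trailing r as covariate, which all 6 GF arrays but only 2 of 6 CTRL arrays carry, the genes at an unadjusted p under 0.05 numbered 741 here and 822 in CCR7- cells, both under the 997 that chance gives, although the changes of Naf1, Birc5 and Atxn10 stayed about as large. Averaged over both stages, Naf1 was higher in germ-free mice by 1.05 ± 0.14 (adjusted p 0.0174), again a fit chosen after seeing the data. The cell cycle list, to which Birc5 belongs, had a median of 0.18 (camera adjusted p 0.0123, and adjusted p = 0.915 with an estimated correlation); 1 of 39 rose, 2 did adjusted over the list alone, and the call ended without CTRL CCR7+ replicate 3 (0.396) or GF CCR7+ replicate 2 (0.108). Both background comparisons of a stage use the same 3 CTRL arrays and are not independent of each other.

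**Figure D4:**
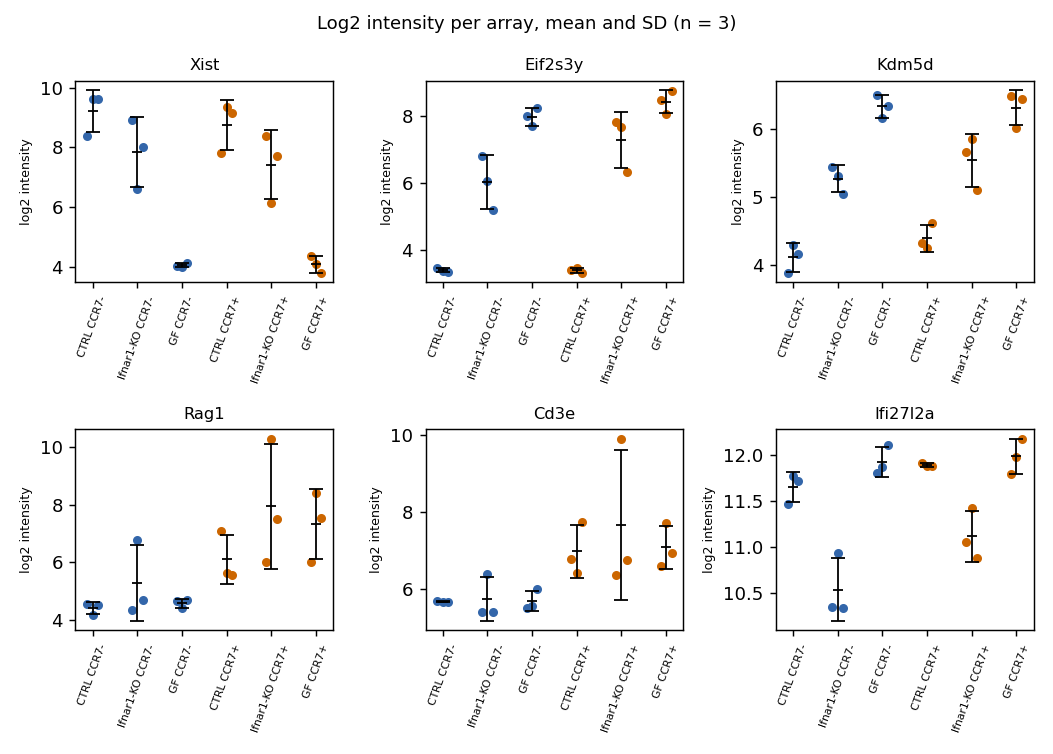
Log2 intensity on each array (points, y axis) with group mean and SD (bars, n = 3) for 6 genes, by group on the x axis. Xist lay at 3.99 to 4.13 on germ-free CCR7- arrays, and Rag1 reached 10.31 on Ifnar1-KO CCR7+ replicate 2.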

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

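Camera called 14 lists for the difference of the maturation change between Ifnar1-KO and CTRL, with 0 members called over all genes. Their median differences were 0.20 for costimulation, 0.31 for mature DC genes, 0.18 for NF-kB, 0.15 for migration, 0.33 for chemokines, 0.33 for identity, 0.22 for MHC class II, 0.33 for type I interferon stimulated, 0.44 for interferon gamma stimulated, 0.056 for interferon receptors and sensors, 0.28 for cell cycle, 0.20 for cholesterol synthesis, 0.15 for survival and 0.14 for immediate early genes. For GF minus CTRL it called 7 lists, again with 0 members: 0.16 for costimulation, 0.31 for mature DC genes, 0.10 for migration, 0.30 for identity, 0.085 for type I interferon stimulated, 0.12 for interferon gamma stimulated and 0.31 for cell cycle. None held with an estimated correlation. For GF only the mature DC and cell cycle calls stood whichever single array was left out; for Ifnar1-KO those of costimulation, NF-kB, chemokines, interferon receptors and sensors, cholesterol synthesis and immediate early genes ended without at least 1 array. All 3 patterns weighed here, and every test of them except the splits, were chosen only after the results were seen.

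The mature DC list was higher on CTRL CCR7- arrays than on the 6 other CCR7- arrays by 0.50. Fully mature cells in the CTRL CCR7- sort could give this: a share of 3.17% would be needed (quartiles over members 1.20% and 5.24%). Of 19 abundant transcripts of CCR7+ cells, 11 (57.9%) lay more than 2 SE below the level that share needs, but only 2 (10.5%) at the lower quartile, so the test cannot tell. This verdict was set after the result was seen. Some of the 19, such as Stat4, Nudt17, Anxa3 and Fscn1, belong to the mature DC list that set the share, so the test is partly circular. A difference between the backgrounds gave an exact permutation p of 0.0714 over 84 relabelings, which cannot tell either, and GF CCR7- replicate 1 read like CTRL. Sex was not separable from background. In GF the lower arrays, replicates 2 and 3, were also those apart on the second component, but in Ifnar1-KO the lower arrays, replicates 1 and 3 (7.14 and 7.07), were not apart, and replicate 2, which was, had the highest mean (7.39).

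Sex-linked genes led GF minus CTRL. If the mice differed in sex, X-linked genes that escape inactivation should be lower in GF; their median was -0.53 (Kdm6a -0.94, Kdm5c -0.67, Eif2s3x -0.39, Ddx3x -0.23), which fits. Ifnar1-KO arrays carried both Xist (7.85 ± 1.16 in CCR7- cells, mean ± SD, n = 3) and Y-linked Eif2s3y, as pools of both sexes might. Comparisons between backgrounds may therefore include sex effects.

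Of 20 thymocyte markers, 5 rose on CCR7+ arrays in CTRL, 4 in Ifnar1-KO and 3 in GF, and the list calls were lost with an estimated correlation (adjusted p 0.565, 0.373 and 0.484). Their deviations from group means went together across arrays, with a mean r of 0.732 against a median of 0.00368 and a 95th percentile of 0.0547 for 10000 matched random lists (percentile 100). Without Ifnar1-KO CCR7+ replicate 2 the mean r was 0.454 and without both Ifnar1-KO replicate 2 arrays 0.439 (95th percentiles 0.0572 and 0.0586), so that array carries part of it, not all. That fits thymocytes, or their RNA, carried in varying amounts among sorted cells; expression by the dendritic cells themselves was not tested.

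Regrouping the arrays gave these counts. For maturation in CTRL, Ifnar1-KO and GF, 1 of 10 splits, the real one, had as many calls, and the highest other had 0. Every other such split mixes CCR7+ and CCR7- arrays within a group. This adds the stage difference to the spread, so the 0 carries little information. For the differences, 100 of 100 relabelings had at least the 0 real calls, and the highest other had 3 for Ifnar1-KO and 6 for GF. With 0 real calls the 100 of 100 was fixed in advance and decides nothing. Ifnar1-KO minus CTRL in CCR7- cells had 10 of 10 splits with at least its 0 calls (highest other 0), again fixed in advance. In CCR7+ cells it had 2 of 10 with at least 3 (highest other 5). GF minus CTRL had 1 of 10 in CCR7- cells (highest other 2) and 1 of 10 in CCR7+ cells (highest other 0). With 3 arrays against 3, 10 splits are too few for a share under 0.05.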

How the results depend on the processing

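The maturation counts stayed within 1.5 times their value but varied: CTRL (5218) gave 7209 with array weights and 3736 without both CTRL replicate 2 arrays, and with only the groups compared Ifnar1-KO (4036) gave 2937 and GF (4256) 3313. Leaving out 1 array gave 4083 to 4951 calls for CTRL, 3362 to 3879 for Ifnar1-KO, 3638 to 3916 for GF and 0 to 0 for the differences. The size difference ranged from -0.33 to -0.15 for Ifnar1-KO and from -0.23 to -0.09 for GF, and list calls from 87 to 108. The small background counts moved. Ifnar1-KO minus CTRL in CCR7- cells (0 calls) gave 3 with an intensity trend, 5 with array weights, 1 with genes at or above the median level, 3 with centred arrays, 1 without both Ifnar1-KO replicate 2 arrays, and 0 to 2 with 1 array left out. In CCR7+ cells (3) it gave 1 with the trend, 5 with array weights, 0 with only the groups compared, 1 with the replicate block, 1 with the trailing r as covariate, and 1 to 7 with 1 array left out. GF minus CTRL in CCR7- cells (3) gave 8 with array weights, 5 without both CTRL replicate 2 arrays, 7 without both Ifnar1-KO replicate 2 arrays, 0 without sex-linked genes, and 3 to 41 with 1 array left out. In CCR7+ cells (6) it gave 1 with only the groups compared, 3 with the trailing r, 10 without both Ifnar1-KO replicate 2 arrays, 3 without sex-linked genes, and 2 to 13 with 1 array left out. The 97 list calls became 62 with genes at or above the median level and 22 with an estimated correlation; without both Ifnar1-KO replicate 2 arrays, or without the CCR7+ one, 1 list, thymocyte markers in Ifnar1-KO minus CTRL CCR7+ cells, was called in the opposite direction. The replicate block kept 14 of 15 list calls for maturation in CTRL, 12 of 14 in Ifnar1-KO, 12 of 13 in GF and 2 of 4 for GF minus CTRL in CCR7+ cells. The loss with an estimated correlation follows from allowing for members that vary together; for the others the cause was not tested. Among named maturation genes, 101 of 109 calls in CTRL, 98 of 108 in Ifnar1-KO and 98 of 105 in GF held in every alternative that tested the gene, against 0 of 3 and 1 of 6 for the CCR7+ comparisons of Ifnar1-KO and GF, and 3 of 3 for GF in CCR7- cells. The fit of genes at or above the median level tested only 105 of these calls in CTRL, 104 in Ifnar1-KO and 102 in GF.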

Other observations

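Some metabolic and survival genes were called during maturation in CTRL, in both directions. Idi1, an enzyme of isoprenoid synthesis, rose by 3.89 ± 0.24 (n = 3 per group), within a list of 20 cholesterol synthesis and uptake genes of which 6 rose and 3 fell (11 adjusted over the list alone; camera adjusted p 0.383). Of 12 cholesterol efflux and LXR target genes, 3 rose and 2 fell (5 adjusted over the list alone; camera adjusted p 0.675), with Apol7c at 3.19 ± 0.60, the exporter Abcg1 at 1.69 ± 0.15 and the desaturase Scd2 at -2.63 ± 0.41. Of 17 glycolysis genes, 3 rose and 9 fell (13 adjusted over the list alone): Pfkfb3 rose by 3.11 ± 0.18 and Eno2 by 3.08 ± 0.39, while Ldha changed by -2.58 ± 0.30 and Hk2 by -2.13 ± 0.20. The glycolysis list was below other genes by camera (adjusted p 0.0425, and adjusted p = 0.184 with an estimated correlation), and was not called without CTRL CCR7- replicate 1 (0.0636) or CTRL CCR7+ replicate 1 (0.0711). Of 16 survival and apoptosis genes, 7 rose and 3 fell (10 adjusted over the list alone; camera adjusted p 0.0996), with the death receptor Fas at 4.42 ± 0.50, Birc2 at 2.96 ± 0.25 and Cflar at 1.57 ± 0.20.

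Of 30 pattern recognition and uptake genes, 2 rose and 10 fell in CTRL maturation (14 adjusted over the list alone), with Cd36, the inhibitory Fc receptor Fcgr2b (-2.57 ± 0.21), Nlrp3 (-1.83 ± 0.20) and Nod1 (-1.69 ± 0.32); camera gave an adjusted p of 0.0171, and adjusted p = 0.0825 with an estimated correlation. Of 23 immediate early and dissociation genes, 2 rose and 8 fell (14 adjusted over the list alone), with Egr2 at -3.42 ± 0.38, Nr4a1 at -2.32 ± 0.36 and Fos at -1.74 ± 0.23. Their camera adjusted p was 0.0425, and adjusted p = 0.556 with an estimated correlation, and the call ended without CTRL CCR7- replicate 2 (0.193), CTRL CCR7+ replicate 1 (0.0829), CTRL CCR7+ replicate 3 (0.1) or Ifnar1-KO CCR7- replicate 2 (0.0586). Of 41 genes next to Ifnar1 on chromosome 16, 6 rose and 13 fell (19 adjusted over the list alone); their median was 0.04 and their mean -0.37, and camera, which follows the mean, placed them lower (adjusted p 0.0413, and adjusted p = 0.0816 with an estimated correlation); with the replicate block the list was not called (0.0539).

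Lists of markers of cell types other than thymocytes did not pass camera in CTRL maturation, although single markers changed. Of 15 macrophage markers 1 rose and 4 fell (camera adjusted p 0.155), among them Cd68 at -3.60 ± 0.32. Of 16 CD172a+ DC markers 4 rose and 5 fell (camera adjusted p 0.283), with Ms4a6c at -4.66 ± 0.40, Ccr2 at -3.06 ± 0.18 and the transcription factor Irf4 at 2.39 ± 0.30. Of 13 plasmacytoid DC markers 4 rose and 3 fell (camera adjusted p 0.996), with Spib at 2.48 ± 0.20. Of 15 NK and innate lymphoid cell markers 1 rose, Il7r at 3.10 ± 0.20, and 1 fell (camera adjusted p 0.45). Of 13 B cell markers 0 rose and 1 fell, Fcrla at -2.18 ± 0.14 (camera adjusted p 0.708); their median was 0.08 and their mean -0.11. Of 16 thymic epithelium markers 2 rose and 1 fell (0.0744), of 12 granulocyte markers 1 rose (0.166), of 6 erythroid markers 2 rose (0.163) and of 4 sex-linked genes 0 changed (0.981), each with its camera adjusted p.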
